A study of Arabidopsis thaliana with 12 samples.

How the data were processed

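RNA abundance was measured in roots of 10-day-old Arabidopsis thaliana plants with Affymetrix arrays hybridised with biotin-labelled cRNA made from total RNA, per the labels. The parental line, called P here, is Columbia carrying the promoter of the sulfate transporter gene SULTR1;2 fused to GFP. The slim1-1 and slim1-2 lines are 2 mutants of SLIM1, also known as EIL3, a transcription factor of the EIN3-like family. Plants grew on agar with 1500 µM added MgSO4 (S1500, sufficient sulfate) or on low-sulfate agar with 15 µM (S15), and washed agar alone left about 10 µM of residual sulfate per the labels. Each of the 6 combinations of line and medium had 2 arrays, which the labels call biological replicates, so 12 arrays entered every fit. Groups and replicate numbers were taken from the sample titles.

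The deposited values are intensity values, 1 signal per probe set and array on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The version and the scaling target are not given in the sources used here. Signals ran from 0 to 12184.5. The number of arrays limits the precision of every value.

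Signals under 1 were set to 1 and log2-transformed. A rule set in advance asked for quantile normalization where the array medians differed by more than 0.5 on the log2 scale. They ran from 6.04 to 7.45, a range of 1.41, so quantile-normalized log2 signals were used. Of 22810 probe sets, 64 controls were left out, and 13647 of the other 22746 had a mean log2 signal above the 40th percentile (5.77) and were tested. A linear model with 1 mean per group was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, using eBayes with an intensity trend, 6 residual and 7.76 prior degrees of freedom. Tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over all tested probe sets in 1 comparison, and a probe set was called at 0.05. A call therefore says that the difference exceeded the spread between replicate arrays, pooled over the groups.

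The comparisons were S15 against S1500 in each line, each slim1 line and the mean of both against P on S15, the mean of both against P on S1500, the mean slim1 response minus the parental response, called the difference of response, and slim1-1 against slim1-2 on S15. The comparisons, tests, filter, gene lists, naming rule and most alternatives were fixed before the data were examined. Changes are log2 differences with the standard error (SE) of the fit; group levels are means with SD of log2 normalized signals, n = 2 arrays.

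A group in which every array lay below the highest of 27 Bacillus subtilis control probe sets on that array has only a bound. The fold is then given as at least the bright group's mean over the mean of those control levels.

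The probe annotation used here gives 1 gene for 13513 probe sets, several for 503, and does not list 8794, which are unnamed here. Of the probe sets with 1 gene, 13436 matched the RefSeq table of assembly TAIR10.1, used for current symbols and for which genes neighbour each other. Among tested probe sets, 7332 (53.7%) had 1 gene. Genes were named by this rule: the 10 highest and 10 lowest called changes with 1 gene and no overlap of arrays between groups for the parental response, both slim1 lines against P on S15 and the difference of response, 5 and 5 for the other comparisons, and up to 4 called members per gene list. For the difference of response, no overlap meant that every low-minus-sufficient difference of a slim1 line lay on 1 side of every such parental difference. SLIM1, SULTR1;1, SULTR1;2, SULTR4;1, SULTR4;2 and APR1 to APR3 were to be named whatever their values and were not analysed here, because their probe sets are unnamed here.

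Gene lists were tested with camera from limma at a preset correlation of 0.01 where at least 3 members were tested, and again with an estimated correlation. Of 323 entries in 23 lists, 40 were named here and 29 tested, and 4 lists had at least 3 tested members. Counts of called list members are given over all tested probe sets and adjusted over the list alone.

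The procedure was tested on simulated data with 200 changed among 13647 probe sets. For the parental response, 49.3% of changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, with 5.05% false calls. For the difference of response the shares were 21.9%, 87.1% and 100%. The parental response had the lowest share of false calls among the comparisons, and both slim1 lines against P on S1500 the highest, 7.30%.

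Alternatives were median centring, pseudocounts of 16 and 64, no filter, a filter at the 60th percentile, no intensity trend, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the signals as deposited without normalization between arrays, values raised to the control bound, gene families by symbol stem, and each slim1 line apart on S1500.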

Results

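Root RNA of 3 Arabidopsis lines was compared on sufficient and low sulfate: the parental reporter line P and the mutants slim1-1 and slim1-2, with 2 arrays in each of 6 groups. Median signals ran from 65.65 to 174.95 per array, and slim1-2-S15 replicate 2 was the brightest. The share of probe sets above the control bound ran from 71.8% to 84.6%. Replicates of a group correlated at 0.962 to 0.967 across probe sets and arrays of different groups at 0.955 to 0.972, where genes are not independent replicates. Without normalization between arrays, the median of all tested probe sets shifted by 0.26 on the log2 scale in the parental response, 0.61 in the slim1-2 response, 0.10 for slim1-1 against P on S15, 0.47 for slim1-2 against P on S15, 0.28 for both slim1 lines against P on S15, 0.22 for both on S1500 and -0.37 for slim1-1 against slim1-2. Changes below are relative to quantile-normalized signals, in which these medians lay near 0. SLIM1 itself was not analysed here.

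The parental response asked which transcripts change in roots when sulfate is scarce. BGLU28, a beta-glucosidase gene known to respond to sulfur deficiency, rose on S15 by 7.70 ± 0.204 (SE, n = 2 arrays per group; adjusted p = 7.14e-12 from limma), at least 177-fold, since its S1500 arrays lay below the control bound. SDI2, SULFUR DEFICIENCY INDUCED 2, rose 3.87-fold, from 8.04 ± 0.267 to 10.00 ± 0.00807 (SD, n = 2). AT1G12030 rose at least 31.4-fold, and AT4G31330, AT1G75280, AT2G30540, AT3G56200, CHX16, AT3G49960 and AT1G66760 rose by 3.70, 2.57, 2.26, 1.77, 1.69, 1.68 and 1.59 on the log2 scale. MGL, methionine gamma-lyase, which degrades methionine, rose by 1.14 ± 0.136 (adjusted p = 0.000128). The root hair expansins EXPA7 and EXPA18 rose by 0.76 and 0.78, so 2 of 2 tested root hair markers rose.

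Of 21 listed genes of aliphatic glucosinolate synthesis, a pathway that makes sulfur-rich defence compounds from methionine, the 3 tested fell in P. BCAT4, which starts methionine side-chain elongation, changed by -5.12 ± 0.106 (34.7-fold lower; adjusted p = 1.33e-12 from limma), from 11.22 ± 0.0348 to 6.10 ± 0.239 (SD, n = 2). UGT74C1 changed by -2.22 ± 0.148 and GSTU20 by -1.97 ± 0.116, so 3 of 3 tested members fell, also when adjusted over the list alone (camera adjusted p = 1.44e-15, and adjusted p = 0.000689 with an estimated correlation). UGT74B1, the glucosyltransferase of the core glucosinolate structure, fell by 0.93 ± 0.114. Among other genes of the naming rule, AT2G25450, AT1G21440, AT2G28780, AT2G23910, AT3G14280 and AT3G57010 fell, with log2 changes of -2.22, -2.21, -1.77, -1.64, -1.35 and -1.34.

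Of 23 listed genes of sulfate assimilation and cysteine and glutathione synthesis, 3 were tested, and they moved both ways in P. ATPS4, an ATP sulfurylase that activates sulfate, fell by 2.46 ± 0.0936 (5.49-fold; adjusted p = 4.63e-10 from limma), whereas ATPS3, another ATP sulfurylase, rose by 0.75 ± 0.141 (adjusted p = 0.0061). SIR, sulfite reductase, fell by 0.50 ± 0.114 (adjusted p = 0.0237). With 1 of 3 tested members higher and 2 lower, also when adjusted over the list alone, the list was called lower by camera (adjusted p = 0.0159), but not with an estimated correlation (adjusted p = 0.0766 with an estimated correlation). In methionine metabolism MGL rose, CBL (cystathionine beta-lyase) fell by 0.56 ± 0.0837 and 2 of 4 tested members, HMT1 and MMT, did not pass (camera adjusted p = 0.829). The auxin list had 0 of 3 tested members called, and 1 higher, IAA18, when adjusted over the list alone (camera adjusted p = 0.574). UGT78D2, a flavonoid glucosyltransferase, fell by 0.66 ± 0.143, and the shoot marker RCA, rubisco activase, fell by 0.43 ± 0.102 (adjusted p = 0.0287). PYK10, EIN3, PYE, GSTU25, CCS, LHCB4.1 and SGN3, tested members of the myrosinase, EIN3 family, iron, glutathione S-transferase, antioxidant, shoot and endodermis lists, were not called. The lists of sulfate transporters, jasmonate, ethylene, nitrate, phosphate, stele, meristem and root cap genes had 0 members named here and were not analysed here.

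In all, 524 of 13647 probe sets were called in P, 243 higher and 281 lower, with 123 changed at least 2-fold, and 221 of the 524 had 1 gene. Among probe sets unnamed here, the 2 highest changes were 6.34 and 6.14 and the 2 lowest -4.58 and -3.93. Without P-S1500 replicate 1, P-S15 replicate 1 or P-S15 replicate 2 the count was 270, 337 or 272, and without normalization between arrays it was 65, with 40 higher and 25 lower. There 12 of the 29 named calls were lost, those of ATPS3, SIR, CBL, MGL, UGT74B1, EXPA7, EXPA18, RCA, UGT78D2, AT2G23910, AT3G14280 and AT3G57010. SIR also lost its call with no filter, and SIR and RCA lost theirs without the intensity trend. Of the 29 named values, 22 kept their call in every set of arrays in which they were tested; AT1G12030 is among them but fell below the filter, untested, without any single S15 array. ATPS3 lost it without P-S1500 replicate 2 (0.61) or P-S15 replicate 1 (0.70), SIR without P-S1500 replicate 1 (-0.45), P-S1500 replicate 2 (-0.54) or P-S15 replicate 2 (-0.40), UGT78D2 without P-S1500 replicate 1 (-0.54) or P-S15 replicate 2 (-0.56), AT2G23910 (-1.45) and AT2G30540 (2.11) without P-S15 replicate 2, EXPA7 without P-S1500 replicate 1 (0.52) or either P-S15 array (0.74 and 0.79), and RCA without the same 3 arrays (-0.30, -0.47 and -0.40).

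**Figure D1:**
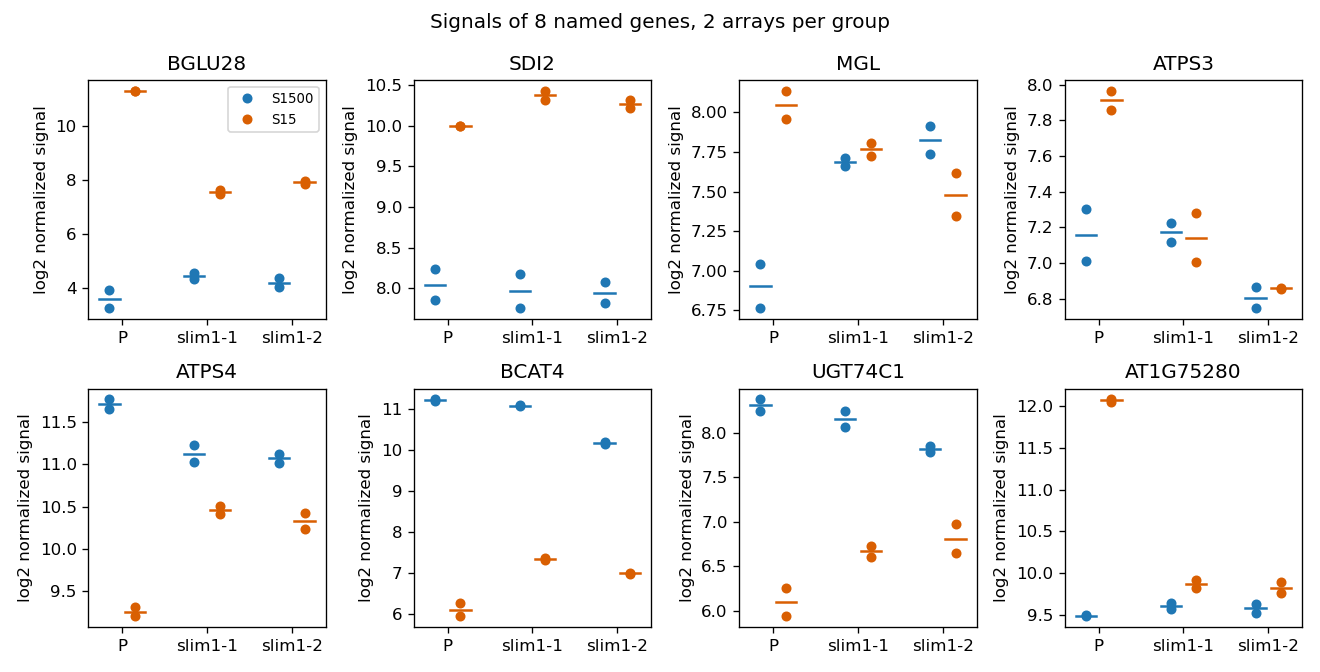
Log2 normalized signals of 8 named genes in P, slim1-1 and slim1-2 on S1500 (blue) and S15 (orange). Each dot is 1 array and each line the mean of the 2 arrays of a group; SDI2 sits near 10 on S15 in all 3 lines, while AT1G75280 reaches 12.07 on S15 in P and stays below 10 in both slim1 lines.

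The response of each slim1 line asked which changes also occur in mutants of SLIM1. SDI2 rose by 2.41 ± 0.146 in slim1-1 and 2.32 ± 0.146 in slim1-2 (adjusted p = 1.65e-07 and 2.89e-07 from limma, n = 2 arrays per group). BGLU28 rose 8.59-fold in slim1-1 and by 3.71 ± 0.204 in slim1-2, and AT1G12030 rose at least 64.5-fold in slim1-1 and by 4.88 ± 0.482 in slim1-2. On S1500 in slim1-2, 1 of the 2 arrays lay below the control bound for BGLU28 and for AT1G12030, so no fold is given there, and the AT1G12030 arrays had an SD of 1.1. In slim1-1 and slim1-2, BCAT4 changed by -3.76 ± 0.106 and -3.19 ± 0.106, UGT74C1 by -1.49 and -1.004, and GSTU20 by -1.14 and -0.96, so 3 of 3 tested aliphatic glucosinolate genes fell in each line, also when adjusted over the list alone (camera adjusted p = 1.44e-15 and 2.03e-11; adjusted p = 0.000689 and 0.00172 with an estimated correlation). ATPS4 changed by -0.67 ± 0.0936 and -0.74 ± 0.0936, and SIR by -0.50 and -0.61, so 2 of 3 tested sulfate assimilation genes fell in each line, also when adjusted over the list alone (camera adjusted p = 0.000586 and 0.00121; adjusted p = 0.0225 and 0.0284 with an estimated correlation). AT2G25450 changed by -2.09 and -1.99 and AT1G21440 by -2.06 and -1.57. In slim1-1, AT2G28780 changed by -1.26 and UGT74B1 by -0.63, and AT4G31330 and EXPA8 rose by 1.41 and 1.36. In slim1-2, AT1G09310 changed by -3.78 ± 0.241 (at least 10.0-fold lower), LHCB4.2, a light-harvesting protein gene, by -1.65 ± 0.153 and the shoot marker RCA by -0.72 ± 0.102, with LHCB4.1 not called (-0.41, adjusted p = 0.192) though lower when adjusted over the list alone, while AT4G31330 and AT4G14020 rose by 1.41 and 1.28. EXPA7 and EXPA18 were not called in either line, and no tested member of the methionine or auxin lists was called (camera adjusted p = 0.598 and 0.747 in slim1-1, 0.278 and 0.278 in slim1-2). Adjusted over the list alone, 1 methionine gene was lower in slim1-1 and 2 in slim1-2.

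Calls numbered 300 in slim1-1 (110 higher, 190 lower) and 416 in slim1-2 (145 higher, 271 lower). With median centring slim1-1 had 67 higher and 209 lower, with no filter slim1-2 had 96 higher, and without normalization between arrays it had 28 higher and 7 lower. Without slim1-1-S1500 replicate 1 or 2 the slim1-1 count was 137 or 160, and without slim1-1-S15 replicate 1 or 2 it was 177 or 172. Without slim1-2-S1500 replicate 1 or 2 the slim1-2 count was 270 or 269, and without slim1-2-S15 replicate 1 or 2 it was 252 or 196. Without normalization between arrays 8 of 14 named calls were lost in slim1-1 and 8 of 15 in slim1-2, among them UGT74C1, GSTU20, ATPS4 and SIR in each line, whereas BGLU28, SDI2 and BCAT4 kept theirs. With no filter AT4G31330 lost its call in each line, SIR in slim1-1 and AT4G14020 in slim1-2, and without the intensity trend SIR and AT4G31330 lost theirs in slim1-1. AT1G12030 fell below the filter without any single S15 array, and AT1G09310 without any single P or slim1-2-S1500 array, and they were not tested there. In slim1-1, AT4G31330 was 0.75 without slim1-1-S1500 replicate 2 and lost its call without slim1-1-S15 replicate 1 (1.38) or 2 (1.45), EXPA8 lost it without slim1-1-S1500 replicate 1 (1.00), UGT74B1 without slim1-1-S1500 replicate 2 (-0.57) or slim1-1-S15 replicate 2 (-0.58), and SIR without either P-S1500 array (-0.50 each), slim1-1-S1500 replicate 1 (-0.32) or slim1-1-S15 replicate 1 (-0.48) or 2 (-0.52). In slim1-2, SIR lost it without slim1-2-S1500 replicate 1 (-0.50) or slim1-2-S15 replicate 1 (-0.53), AT4G14020 without slim1-2-S1500 replicate 1 (1.29) or 2 (1.27) or slim1-2-S15 replicate 2 (1.03), and AT4G31330 without slim1-2-S1500 replicate 2 (1.29) or slim1-2-S15 replicate 1 (1.497) or 2 (1.33).

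Many responses were called in all 3 lines, 41 higher and 98 lower, of which 17 and 38 had 1 gene. SDI2, AT1G12030, BGLU28, BCAT4, GSTU20, UGT74C1, SIR, AT2G25450 and AT1G21440 were among them. P shared 63 higher and 132 lower calls with slim1-1, against 1.96 and 3.91 for independent lists of those sizes, and 61 and 120 with slim1-2, against 2.58 and 5.58. The slim1 lines shared 53 higher and 123 lower calls, against 1.17 and 3.77.

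The difference of response tested directly whether the slim1 lines responded other than P. BGLU28 rose less in the slim1 lines, by -4.29 ± 0.249 (adjusted p = 3.58e-07 from limma), or -4.07 with values below the control bound raised to it. AT1G75280, which rose 5.95-fold in P, differed by -2.32 ± 0.0972 (adjusted p = 1.87e-08), AT4G31330 by -2.29 ± 0.341 and MGL by -1.27 ± 0.167. ATPS4 and BCAT4, which fell in P, fell less in the slim1 lines, by 1.75 ± 0.115 (adjusted p = 9.82e-07) and 1.64 ± 0.13 (adjusted p = 8.1e-06). GSTU20 and UGT74C1 differed by 0.92 and 0.97, so 3 of 3 tested aliphatic glucosinolate genes differed upward, also when adjusted over the list alone (camera adjusted p = 1.01e-10; adjusted p = 0.00207 with an estimated correlation). The root hair markers EXPA7 and EXPA18 differed by -0.86 and -0.81. AT4G33960 and AT3G49960 differed by -1.52 and -1.54. AT3G49960 differed by line on S1500, in comparisons chosen after seeing the data. It was 1.15 above P in slim1-2 (adjusted p = 0.00357 from limma) and 0.09 above P in slim1-1 (adjusted p = 0.91). The sulfate assimilation list had ATPS4 called higher, with 1 higher and 1 lower when adjusted over the list alone. The methionine list had MGL called lower, with 1 higher and 1 lower when adjusted over the list alone, and the auxin list had 0 called (camera adjusted p = 0.331, 0.534 and 0.262). For SDI2 the difference was 0.41 (95% interval 0.03 to 0.79, adjusted p = 0.493), for AT2G25450 0.18 (-0.24 to 0.59, adjusted p = 0.859) and for SIR -0.06 (-0.36 to 0.24, adjusted p = 0.951), none of which passed.

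The difference of response was called for 128 probe sets, 39 higher and 89 lower, or 24 and 59 without the intensity trend. Of these, 98 had been called in P and moved less in the slim1 lines, 70 of them higher and 28 lower on S15 in P, 3 had been called in P and moved further, and 27 were not called in P. Independent lists would share 1.58 and 0.803 calls that moved less, for those higher and lower in P. The difference of response contains the P arrays with the opposite sign, which tilts this overlap toward smaller responses. In 100 simulations with those arrays shared, chosen after seeing the data, calls that moved less averaged 0.07 (at most 1) for unchanged groups and 0.18 (at most 3) for the same response in all lines, but few differences are called there. Part of the excess may therefore come from the shared P arrays. The covariance of the 2 sets of changes was -0.0575, against -0.0244 and -0.0243 simulated. Their correlation was -0.692, between the simulated -0.817 for unchanged groups and -0.452 for the same response. Without P-S1500 replicate 1 or P-S15 replicate 2 the count was 58 or 64, and without normalization between arrays it was 11, with 19 of 23 named calls lost and those of BGLU28, AT1G75280, AT4G31330 and ATPS4 kept. With no filter 8 named calls were lost, EXPA7, UGT74C1 and UGT74B1 among them, and 7 without the intensity trend. Of 23 named values 8 kept their call whichever array was left out, those of BGLU28, AT1G75280, AT4G31330, MGL, ATPS4, BCAT4, AT4G33960 and AT3G49960. GSTU20 lost it without P-S1500 replicate 1 (0.86), UGT74C1 without P-S1500 replicate 1 (0.91) or 2 (1.03), P-S15 replicate 2 (0.81) or slim1-1-S1500 replicate 1 (0.93), EXPA18 without any single P array (-0.84 to -0.78), and EXPA7 (-0.89 to -0.62) unless the array left out was P-S1500 replicate 2, slim1-1-S1500 replicate 1 or slim1-1-S15 replicate 1.

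**Figure D2:**
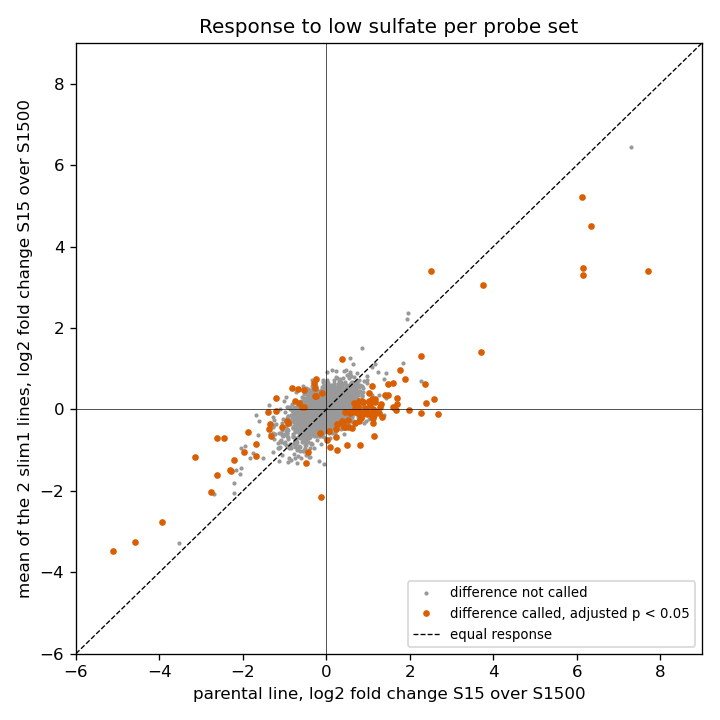
Log2 fold change from S1500 to S15 of each tested probe set in P (x axis) and as the mean of the 2 slim1 lines (y axis). The 128 probe sets with a called difference of response are orange, and the dashed line marks equal responses; most orange points lie nearer to 0 on the y axis than on the x axis.

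On S15 the slim1 lines were compared with P directly. BGLU28 was lower in both, by -3.56 ± 0.176 (11.8-fold; adjusted p = 3.07e-08 from limma), as were AT1G75280 (-2.22 ± 0.0687), AT4G31330 (-2.64 ± 0.241), AT2G25510 (-1.95 ± 0.198) and AT5G40670 (-1.64 ± 0.0771). AT1G09310 was lower by -3.64 ± 0.209 (adjusted p = 1.35e-07), with both slim1-2-S15 arrays and 1 of the 2 slim1-1-S15 arrays below the control bound. ATPS4 was higher by 1.14 ± 0.081 (adjusted p = 1.72e-06) and ATPS3 lower by -0.91 ± 0.122 (adjusted p = 0.000721), so sulfate assimilation had 1 of 3 tested members higher and 1 lower, with 2 lower when adjusted over the list alone (camera adjusted p = 0.746). BCAT4, UGT74C1 and GSTU20 were higher by 1.06, 0.65 and 0.51, which is 3 of 3 tested aliphatic glucosinolate genes, also when adjusted over the list alone (camera adjusted p = 3.36e-07; adjusted p = 0.00656 with an estimated correlation). EXPA7 and EXPA18 were lower by -0.74 and -0.58. Of the 2 tested shoot markers RCA was lower by -0.59, also when adjusted over the list alone, and LHCB4.1 differed by -0.19 (adjusted p = 0.543). CHX16 and AT3G27150 were lower by -1.19 and -1.25, and AT1G64370 and AT3G50640 higher by 0.84 and 0.67. The methionine and auxin lists had 0 called members, and the methionine list had 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.746 each). The median and the mean of a list differed in sign for sulfate assimilation and auxin here, for methionine and auxin in the slim1-1 response, for sulfate assimilation and methionine in the difference of response, for sulfate assimilation in slim1-1 against P on S15, and for methionine and auxin in slim1-2 against P on S15, none of them called by camera.

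Calls numbered 296 for both slim1 lines against P on S15, 101 higher and 195 lower. The split was 58 higher and 216 lower with median centring, and 12 higher and 13 lower without normalization between arrays, with 65 higher with no filter and 59 without the intensity trend. Without P-S15 replicate 1 or 2 or slim1-2-S15 replicate 2 the count was 128, 131 or 195. Without normalization between arrays 17 of 25 named calls were lost, ATPS3, UGT74C1, GSTU20, EXPA7, EXPA18, RCA and CHX16 among them, and 5 were lost with no filter and 4 without the intensity trend. Of 25 named values 13 kept their call in every set of arrays in which they were tested, among them AT1G09310, which fell below the filter without any single P or slim1-2-S1500 array. GSTU20 lost it without P-S15 replicate 1 (0.40) or slim1-2-S15 replicate 2 (0.49), UGT74C1 without P-S15 replicate 2 (0.49) or slim1-2-S15 replicate 2 (0.56), RCA without P-S15 replicate 1 (-0.55), and EXPA7 (-0.72 and -0.77) and EXPA18 (-0.56 and -0.60) without P-S15 replicate 1 or 2.

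Each slim1 line was also compared alone with P on S15. BGLU28 was lower by -3.74 ± 0.204 in slim1-1 and -3.38 ± 0.204 in slim1-2, AT1G75280 by -2.19 and -2.24, and ATPS4 was higher by 1.201 and 1.07 (adjusted p at most 2.05e-05 from limma, n = 2 arrays per group). petB, the plastid gene for cytochrome b6, was higher in slim1-2 by 0.95 ± 0.0949 (adjusted p = 7.39e-05). The root hair markers EXPA7 and EXPA18 were lower in slim1-1, by -0.91 and -0.89, EXPA7 not without P-S15 replicate 1 (-0.88) or slim1-1-S15 replicate 2 (-0.81). In slim1-2 they differed from P by -0.58 (adjusted p = 0.0793) and -0.27 (adjusted p = 0.344), 0 of 2 called and 2 lower when adjusted over the list alone. Between the lines EXPA18 differed by -0.62 (adjusted p = 0.0531), which did not pass. Of the 3 tested aliphatic glucosinolate genes 1 was higher in slim1-1, and 3 when adjusted over the list alone (camera adjusted p = 1.01e-06; adjusted p = 0.00799 with an estimated correlation), and 3 were higher in slim1-2, also when adjusted over the list alone (camera adjusted p = 6.56e-07; adjusted p = 0.00738 with an estimated correlation). There were 219 calls for slim1-1 (57 higher, 162 lower) and 211 for slim1-2 (72 higher, 139 lower). With median centring these were 36 higher and 186 lower, and 43 higher and 131 lower. With no filter 37 and 35 were higher, and without the intensity trend 35 were higher in slim1-2. Without normalization between arrays the splits were 2 higher and 11 lower, and 6 higher and 7 lower, with 9 of 14 and 8 of 14 named calls lost, those of ATPS4 in slim1-1 and petB in slim1-2 among them. Without P-S15 replicate 1 or 2 or slim1-1-S15 replicate 2 the slim1-1 count was 130, 122 or 130, and without P-S15 replicate 1 or 2 or slim1-2-S15 replicate 1 or 2 the slim1-2 count was 90, 104, 124 or 94. The 2 comparisons shared 28 higher and 74 lower calls, against 0.301 and 1.65 for independent lists and a mean of 0.02 and 0.02 (at most 1 and 1) in 100 simulations of unchanged groups sharing the P arrays. Unchanged groups give almost no calls, so these simulated counts do not measure what shared arrays add to an overlap of real calls. The shared higher calls numbered 18 without P-S1500 replicate 1 or 2, 14 without P-S15 replicate 1, 17 without slim1-1-S15 replicate 2 and 12 without slim1-2-S15 replicate 2, and the shared lower calls 45 or 40 without P-S15 replicate 1 or 2. The P arrays are too few to split, so part of the excess of shared calls over independent lists may come from the shared controls. The fold changes of the 2 comparisons correlated across genes at 0.725, against 0.499 simulated, with a covariance of 0.0412 against 0.0121 (at most 0.0129) simulated. The simulated covariance holds what the shared P arrays add, so the difference between the 2 covariances estimates what the lines share beyond those arrays.

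On S1500 the slim1 lines were compared with P to find differences present without sulfate shortage. MGL was higher by 0.85 ± 0.118 (adjusted p = 0.00248 from limma), and ATPS4 was lower by -0.61 ± 0.081 (adjusted p = 0.00199), as were BCAT4 by -0.58 ± 0.0921 and UGT78D2 by -0.89 ± 0.124. AT2G23910 was lower by -1.83 ± 0.242. AT4G29780 and STZ were lower by -1.73 ± 0.384 and -1.36 ± 0.292 (adjusted p = 0.0486 and 0.0433 from limma). Replicates 1 and 2 of P-S1500 were at 9.90 and 8.37 for AT4G29780 and at 10.54 and 9.16 for STZ. The sizes of these 2 differences therefore depend strongly on P-S1500 replicate 1. The plastid gene clpP was higher by 0.98 ± 0.207 (adjusted p = 0.0409). Of the 2 tested shoot markers RCA was lower by -0.59 ± 0.0886, also when adjusted over the list alone, and LHCB4.1 differed by -0.11 (adjusted p = 0.781). These are means of both lines, and some differed by line in a comparison chosen after seeing the data. BCAT4 was -1.04 in slim1-2 (adjusted p = 0.00013) and -0.13 in slim1-1 (adjusted p = 0.744), a called difference of 0.91 (adjusted p = 0.00029). RCA was -0.94 in slim1-1 (adjusted p = 0.000356) and -0.24 in slim1-2 (adjusted p = 0.294), a called difference of -0.71 (adjusted p = 0.00193). AT2G23910 was -2.65 in slim1-2 (adjusted p = 0.000149) and -1.01 in slim1-1 (adjusted p = 0.181), a difference of 1.64 (adjusted p = 0.0063) that was not called without slim1-1-S1500 replicate 1 (1.40) or slim1-2-S1500 replicate 2 (1.36). EXPA18 was higher in slim1-2 by 0.59 (adjusted p = 0.0181), but not without either P-S1500 array (0.61 and 0.56) or slim1-2-S1500 replicate 1 (0.45). As deposited, of these calls by line only that of AT2G23910 in slim1-2 was kept. Of the aliphatic glucosinolate genes 1 of 3 was lower, and 3 when adjusted over the list alone (camera adjusted p = 6.59e-05; adjusted p = 0.0192 with an estimated correlation). Sulfate assimilation had 1 of 3 lower, also when adjusted over the list alone (camera adjusted p = 0.00168; adjusted p = 0.0317 with an estimated correlation). The methionine list had MGL called higher, also when adjusted over the list alone, and the auxin list had 0 called (camera adjusted p = 0.0941 and 0.108). The calls numbered 147, 44 higher and 103 lower, but only 21 without P-S1500 replicate 1, and 85, 86 or 89 without slim1-1-S1500 replicate 1 or 2 or slim1-2-S1500 replicate 2. With no filter 25 were higher and 44 lower, and without the intensity trend 23 and 41. Of 15 named values 1, that of ATPS4, kept its call whichever array was left out, and MGL (0.71), BCAT4 (-0.56), UGT78D2 (-0.77), RCA (-0.46) and AT2G23910 (-1.73) lost it without P-S1500 replicate 1. Without normalization between arrays 5 were higher and 3 lower, and 14 of 15 named calls were lost, that of ATPS4 included; 9 were lost with no filter and 7 without the intensity trend.

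The slim1 lines were set against each other on S15 to find where the alleles differ. petB was lower in slim1-1 than in slim1-2 by -0.82 ± 0.0949 (adjusted p = 0.0022 from limma, n = 2 arrays per group), and AT4G12500 was higher by 1.15 ± 0.121 (adjusted p = 0.0022). These 2 of 8 named values kept their calls whichever array was left out. The 25 calls were 8 higher and 17 lower in slim1-1, 5 and 4 with no filter and 1 and 2 without the intensity trend, and without slim1-1-S15 replicate 1 or 2 or slim1-2-S15 replicate 1 or 2 they numbered 6, 12, 8 or 8. Without normalization between arrays 0 were higher and 1 lower, and all 8 named calls were lost, those of petB and AT4G12500 included.

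**Figure D3:**
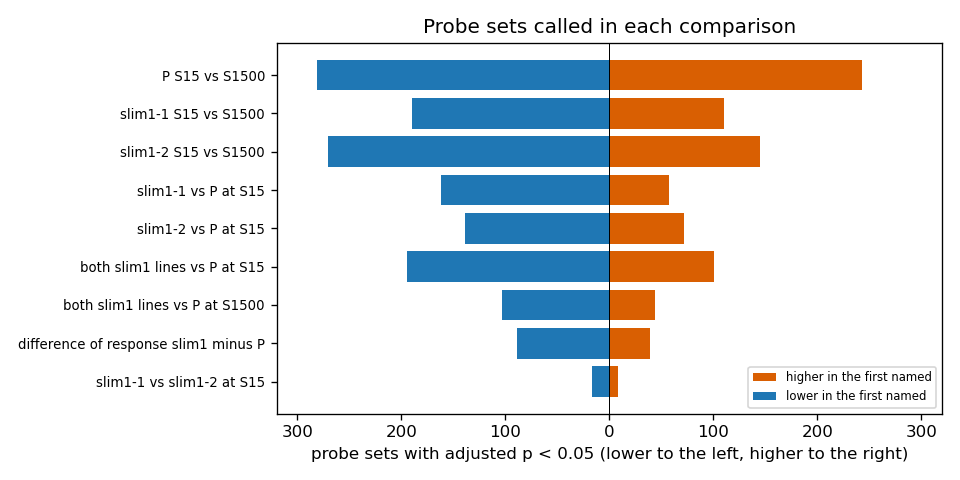
Number of probe sets called in each comparison, lower to the left (blue) and higher to the right (orange) in the group named before "vs", or in the slim1 lines for the difference of response. The parental response has the most calls, 281 lower and 243 higher, and slim1-1 against slim1-2 on S15 the fewest, 17 lower and 8 higher.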

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

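The petB tests, the test of its neighbours and the comparisons of single slim1 lines on S1500 were chosen after the result was seen; the others were chosen before. The low-sulfate response differed between the slim1 lines and P for 128 probe sets by the test of the difference itself, and 23 named values drew attention for that reason. The slim1 response minus the P response was negative for BGLU28 (-4.29), AT1G75280 (-2.32), AT4G31330 (-2.29), AT1G70880 (-1.80), AT2G25510 (-1.67), AT3G49960 (-1.54), AT1G66760 (-1.53), AT4G33960 (-1.52), CHX16 (-1.41), AT5G36270 (-1.32), MGL (-1.27), EXPA7 (-0.86) and EXPA18 (-0.81). It was positive for ATPS4 (1.75), BCAT4 (1.64), AT4G03100 (1.35), ATC (1.18), AT3G14280 (0.99), UGT74C1 (0.97), AT5G45210 (0.96), GSTU20 (0.92), AT3G57010 (0.68) and UGT74B1 (0.64), all on the log2 scale. These are not differences of level, and they also hold differences on S1500. MGL was higher than in P on S1500, by 0.78 in slim1-1 and 0.92 in slim1-2. For both lines together UGT74B1 was lower than in P on S1500 by -0.49 and differed by 0.15 on S15, not called. Of these 23, 15 lost their call when some single array was left out.

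These differences mostly made the response smaller in the slim1 lines. Such differences did not need the bright slim1-2-S15 replicate 2 array. Without any slim1-2 array, the slim1-1 minus P difference of response had 58 calls of its own, 14 higher and 44 lower. The median over the 128 was then 0.931 of that with all arrays. The 128 had been chosen with the same P and slim1-1 arrays, which holds this ratio near 1 for chance differences too. Quantile normalization in place of median centring does not account for most of them, since 93.0% were called again in the same direction with median centring. Both methods bring the array centres together, so this does not test normalization between arrays itself. As deposited, 19 of the 23 named calls were lost. For a weaker response in general the 2 directions of the test differed: over the 300 probe sets called in slim1-1 the P response exceeded that of slim1-2 by a median of 0.08 (95% interval 0.02 to 0.14), but over the 416 called in slim1-2 it exceeded that of slim1-1 by 0.00585 (-0.02 to 0.03). These 2 intervals come from resampling probe sets as if they were independent, and they do not measure variation between arrays. The 300 and the 416 probe sets were each called in a slim1 line. They leave out responses not called there, such as those of EXPA7 and EXPA18, and so can miss a weaker response. This test therefore cannot decide whether choosing genes by their parental response, whose arrays the difference of response shares, accounts for a general attenuation. An effect of the slim1 genotype was not tested separately.

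petB was higher in slim1-2 than in every other array on both media, at 11.40 to 11.73 against 10.52 to 10.80. More plastid RNA or shoot tissue in the slim1-2 samples is argued against as the whole of this difference, because the other 54 plastid-encoded probe sets had a median difference from slim1-1 of -0.0756 against 0.88 for petB. Against P on S15 all 55 had a median of 0.398 in slim1-2 and 0.282 in slim1-1, with petB at 0.95 and 0.13. The median of the other 54 was 7.70 and 8.51 in the 2 slim1-2-S1500 arrays, so a smaller plastid difference is not excluded. On S1500 the nuclear shoot markers RCA and LHCB4.1 were lower in slim1-1 than in slim1-2 by -0.71 and -0.69. So was LHCB4.2 by -0.82, a nuclear gene outside the shoot list that was named for its slim1-2 response. LHCB4.1 lost its call without slim1-1-S1500 replicate 1 (-0.62). Neither LHCB4 gene was called without slim1-1-S1500 replicate 2 (-0.76 and -0.69) or slim1-2-S1500 replicate 1 (-0.77 and -0.79) or 2 (-0.62 and -0.86). However, in slim1-2 RCA, LHCB4.1 and LHCB4.2 differed from P on S1500 by -0.24, 0.24 and -0.01, none called, against 1.01 for petB. Without the bright array the lowest slim1-2 array still lay 0.609 above the highest other one, and the tested genes within 5 places of petB averaged 0.63 higher in slim1-2 (exact one-sided p = 3.10e-06 over sets of plastid genes), but psbT, rpoA, psbH and psbB had been seen to lead the list before that test and its 5 places were chosen, and the mean was 0.28 within 8 places and 0.18 within 10. That p treats plastid genes as independent units and does not measure variation between arrays. None of the 6 neighbours was called between the slim1 lines on S15 (adjusted p from limma 0.217 for psbH to 0.997 for clpP). A change in the stretch of the plastid genome around petB or its transcripts stays a candidate explanation that these same values cannot establish, and a plastid difference unrelated to SLIM1 was not tested.

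On S1500 ATPS4 and MGL looked shifted toward the low-sulfate state in slim1-1 (-0.59 and 0.78, adjusted p = 0.00991 and 0.0193 from limma) and slim1-2 (-0.64 and 0.92), and BCAT4 in slim1-2 (-1.04, against -0.13 in slim1-1). As deposited none of these calls was kept, and in slim1-1 ATPS4 lost its call without P-S1500 replicate 1 (-0.64) or 2 (-0.52) or slim1-1-S1500 replicate 1 (-0.49), and MGL without P-S1500 replicate 1 (0.64, and 0.78 in slim1-2) or slim1-1-S1500 replicate 1 (0.80) or 2 (0.75). Other genes were divided. UGT78D2, which changed by -0.66 in P on S15, shared this shift. On S1500 it was lower by -0.78 in slim1-1 and -0.999 in slim1-2 (adjusted p = 0.0255 and 0.00241 from limma). For both lines together that call was lost without P-S1500 replicate 1. UGT74B1 and AT3G14280, which also fell in P, were called lower on S1500 in slim1-2 but not in slim1-1. AT5G40670, at 9.31 on S1500 and 10.48 on S15 in P, moved the opposite way on S1500. It was lower by -0.61 in slim1-1 and -0.67 in slim1-2 (adjusted p = 0.00519 and 0.00116 from limma). SDI2 differed by -0.08 and -0.10, not called. The 2 unnamed probe sets that rose most in P were higher in the mean of both lines, by 1.70 and 2.32. Over genes called in slim1-2, slim1-1 minus P on S1500 had a median of 0.0158 signed by the slim1-2 response (95% interval -0.02 to 0.05), and 0.0407 (-0.01 to 0.08) with median centring. With genes chosen in slim1-1 the median for slim1-2 was 0.10 (0.06 to 0.13), and 0.12 (0.08 to 0.18) with median centring. These intervals of medians also come from resampling probe sets and leave out variation between arrays. Because the interval includes 0 in 1 direction of the test, a shift of slim1-1 over many genes cannot be told apart from chance values of the shared parental arrays or from the normalization.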

How the results depend on the processing

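The signals as deposited and the values raised to the control bound were chosen after seeing the data. Quantile normalization, planned as an alternative, became the main setting by the rule on array medians, and every alternative fixed in advance was run. None of 157 named values changed direction under any setting; calls lost were 1 with median centring, 3 and 5 with pseudocounts of 16 and 64, 35 with no filter, 30 without the intensity trend, 103 as deposited and 0 when raised to the bound, and 1 of the 110 testable above the 60th percentile. With no filter, slim1-2 against P on S15 had 135 calls, both slim1 lines on S1500 69, slim1-1 against slim1-2 9, and the shared higher calls were 16. Without the intensity trend these were 130, 64, 3 and 15, and the difference of response had 83. With median centring the shared higher calls were 15. As deposited, the parental, slim1-1 and slim1-2 responses had 65, 24 and 35 calls, slim1-1 and slim1-2 against P 13 and 13, both on S15 25, both on S1500 8, the difference of response 11, slim1-1 against slim1-2 1, and the shared calls were 2 higher and 6 lower. The cause was not tested. Leaving out 1 array, with the lone array assumed to vary like the others, gave 270 to 556 calls in P, 137 to 321 in slim1-1, 196 to 387 in slim1-2, 122 to 225 and 90 to 230 for slim1-1 and slim1-2 against P, 128 to 307 for both on S15, 21 to 162 on S1500, 58 to 124 for the difference of response and 6 to 35 between alleles. AT1G12030, AT1G09310, EXPA8 and AT4G01390 fell below the filter without some arrays and have no value there. The shared calls of slim1-1 and slim1-2 against P numbered 12 to 32 higher and 40 to 75 lower. The sulfate assimilation list in P was no longer called with an estimated correlation (adjusted p = 0.0766). As deposited, the methionine list on S1500 and the sulfate assimilation list in the difference of response, not called otherwise, were called. The replicate numbers were not taken to pair the arrays, because not every pair of groups correlated above 0.1. Deviations of same-numbered arrays correlated at -0.118 to 0.231 over 15 pairs of groups, above 0.1 in 4. Of the 12 arrays 10 correlated best with their own number, a weak hint of some pairing that the labels do not state. The 2 arrays of a group have mirrored deviations and always give the same answer, so these are not 12 separate results. With the replicate number as a block the counts were 554, 310, 408, 222, 230, 312, 148, 132 and 32 for the parental, slim1-1 and slim1-2 responses, slim1-1, slim1-2 and both against P on S15, both on S1500, the difference of response and the alleles, with 4 named calls lost. Signals below the control bound limit folds to lower bounds.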

Other observations

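The family tests, the comparisons of single slim1 lines on S1500 and the choice of genes in this part came after the values were seen. The other comparisons had been fixed before. Glutathione S-transferase genes of the tau class moved apart. GSTU27 rose in P by 0.89, with its call kept whichever array was left out but not as deposited (adjusted p = 0.282), while GSTU20 fell by 1.97. GSTU28 and GSTU22 rose by 0.51 and 0.38, but GSTU28 not without P-S1500 replicate 1 (0.37), P-S15 replicate 1 (0.59) or P-S15 replicate 2 (0.43), and GSTU22 not without any single P array (0.33 to 0.43). Both lost their calls as deposited (adjusted p = 0.92 each) and without the intensity trend, GSTU28 also with no filter (adjusted p = 0.0536) and GSTU22 with median centring (adjusted p = 0.0577). The enrichment of these 3 of 8 tested (adjusted p = 0.00849 over 39 families, among 7235 background genes) therefore rests on unstable calls.

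In the difference of response 3 families had 2 members called lower each (adjusted p = 0.0118 for each family): GSTU27 and GSTU28 (-0.70 and -0.78, 2 of 8 tested), the beta-glucosidase genes BGLU15 and BGLU28 (-0.65 for BGLU15, 2 of 9) and the expansins EXPA7 and EXPA18 (2 of 7). Of these 6 calls only that of BGLU28 was kept whichever array was left out, and only that one as deposited. GSTU27 lost its call without P-S1500 replicate 2 (-0.59) or P-S15 replicate 2 (-0.69), and GSTU28 without P-S1500 replicate 1 (-0.64) or P-S15 replicate 2 (-0.69). BGLU15 lost it without P-S1500 replicate 1 (-0.52), P-S15 replicate 1 (-0.63) or 2 (-0.67), slim1-1-S1500 replicate 1 (-0.61), slim1-1-S15 replicate 2 (-0.63), slim1-2-S1500 replicate 1 (-0.63) or slim1-2-S15 replicate 1 (-0.60). EXPA18 lost it without any single P array (-0.84 to -0.78), and EXPA7 (-0.89 to -0.62) unless the array left out was P-S1500 replicate 2, slim1-1-S1500 replicate 1 or slim1-1-S15 replicate 1. GSTU20 was called higher by 0.92, though not without P-S1500 replicate 1 (0.86), and EXPA8 differed by 0.71 (adjusted p = 0.481) and was not called. In the other direction the UGT family had 2 of 28 tested members called higher, UGT74C1 and UGT74B1 (adjusted p = 0.0363 for the family). Both of those calls were lost with no filter.

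AT1G09310 was lower than in P on both media in slim1-1 and on S15 in slim1-2. Its log2 signal was 7.64 ± 0.322 and 7.50 ± 0.199 in P on S1500 and S15, 4.43 ± 0.118 and 3.90 ± 0.122 in slim1-1, and 7.61 ± 0.455 and 3.83 ± 0.113 in slim1-2 (SD, n = 2). On S15 both slim1-2 arrays and 1 of the 2 slim1-1 arrays lay below the control bound, so those 2 S15 levels are not exact and their SD may not measure the spread of the transcript. On S1500 slim1-1 was lower than slim1-2 by -3.18 ± 0.241 (adjusted p = 6.51e-06 from limma) and slim1-2 differed from P by -0.03 (adjusted p = 0.974). LHCB4.2, the shoot marker RCA and AT2G25510 followed a like order of groups with smaller differences, but the shoot marker LHCB4.1 was not called against P on S15 (-0.31 in slim1-1, adjusted p = 0.449, and -0.08 in slim1-2, adjusted p = 0.889). On S15 the first 3 were lower than in P by -1.11, -0.65 and -2.02 in slim1-1 and by -1.24, -0.53 and -1.87 in slim1-2, RCA in slim1-2 not without P-S15 replicate 1 (-0.49) or 2 (-0.56) or slim1-2-S15 replicate 1 (-0.53) or 2 (-0.53). On S1500 slim1-1 was lower than P by -0.83 for LHCB4.2 and -0.94 for RCA, and differed by -0.83 for AT2G25510 (adjusted p = 0.181), while slim1-2 differed by -0.01, -0.24 and 0.28, none called. LHCB4.2 lost that call without P-S1500 replicate 1 (-0.69) or slim1-1-S1500 replicate 1 (-0.96) or 2 (-0.70). Whether these genes share a cause was not tested.

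The slim1 lines differed from each other more on S1500, with 231 calls, than the 25 on S15, although the difference between those counts was not tested. The 231 fell to 111 and 113 without slim1-1-S1500 replicate 1 or 2 and to 125 without slim1-2-S1500 replicate 1. Against P on S1500, slim1-1 had 59 calls and slim1-2 302. Without P-S1500 replicate 1 these were 17 and 79, and without slim1-1-S1500 replicate 1 or 2 slim1-1 had 26 or 32; without P-S1500 replicate 2 slim1-1 had 101 and slim1-2 183, and without slim1-2-S1500 replicate 2 slim1-2 had 125. BCAT4 was lower than in P on S1500 in slim1-2 (-1.04 ± 0.106, adjusted p = 0.00013) and differed by -0.13 in slim1-1 (adjusted p = 0.744). The shoot marker RCA was lower in slim1-1 than in slim1-2 there by -0.71 ± 0.102 (adjusted p = 0.00193), and LHCB4.2 by -0.82 ± 0.153 (adjusted p = 0.0118). The LHCB4.2 call was lost without slim1-1-S1500 replicate 2 (-0.69) or slim1-2-S1500 replicate 1 (-0.79) or 2 (-0.86), and as deposited none of these calls on BCAT4, RCA and LHCB4.2 was kept.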
